A study of Mus musculus with 12 samples.

How the data were processed

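Gene expression was measured on 12 Affymetrix Mouse Gene 1.1 ST arrays, on which biotin-labelled targets are hybridised to probes spread along each transcript. The cells were BM67, a prostate cancer cell line derived per the labels from mice that lack Pten in the prostate epithelium. They stably carried either a non-silencing control shRNA (shCtrl) or 1 shRNA against the mouse estrogen receptor alpha gene Esr1 (shERa). Per the labels' protocols, cytosolic lysates were separated on a sucrose gradient by ultracentrifugation, and mRNA bound by more than 3 ribosomes was taken as polysome-associated RNA. Total cytosolic RNA was isolated in parallel. The 4 groups, cytosolic and polysome-associated RNA of shCtrl and shERa cells, had 3 arrays each. The protocol text speaks of 4 profiled replicates, and arrays of 3 per group were analysed here. The replicate numbers were 1, 2 and 3 for shCtrl and 1, 3 and 4 for shERa. The labels do not say whether the replicates were separate transductions, so p-values measure the spread between arrays of these cultures and not between transductions.

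The values were the series' table of processed values, which the authors deposited on what was taken to be a log2 scale, with 1 row per gene. Neither the log base nor the normalization method is given in the sources used here. The values ran from 1.92 to 13.52, and the array medians lay between 5.30 and 5.35. Both features belong to log2 array values after normalization between arrays, and every log2 change below rests on that reading. Scanner files were not used here, so background correction, probe summary and normalization were the authors' own. Values are relative within an array: a general rise or fall of RNA per cell, or of the share of mRNA on polysomes, cannot be seen in them.

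Of the 21115 rows, 20405 carried a mouse gene symbol in the platform annotation. All 20405 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier and were tested. The remaining 710 rows had no symbol in that annotation and entered only 1 alternative. No coordinates are given, because the build behind the arrays' annotation is not named. As a measure of background, the 1094 olfactory receptor rows had a median of 2.99 and a 95th percentile of 4.00 in their mean value. By that measure 13602 genes lay above background. No filter on dim genes was applied in the main test. The number of arrays limits the precision: the median standard error of a knockdown effect was 0.123 on the log2 scale.

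All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit with 4 group means, then eBayes), which leaves 8 residual degrees of freedom per gene. The 4 comparisons were shERa minus shCtrl in cytosolic RNA, the same in polysome-associated RNA, the interaction, and polysome minus cytosolic RNA in control cells. The interaction is the change by knockdown of the polysome-minus-cytosol difference and is called polysome association below. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The classes were defined before the data were examined. Offset genes passed in cytosolic RNA and for the interaction with opposite signs and did not pass in polysome-associated RNA. Abundance genes passed in both RNA types with the same sign and did not pass for the interaction. Translation genes passed in polysome-associated RNA and for the interaction with the same sign and did not pass in cytosolic RNA.

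Because cytosolic change and interaction share arrays, they are correlated by chance. This was measured in 50 simulations without any effect and in 50 with full transmission. In the latter, genes called in either RNA type had their cytosolic change in both, and other genes had none. The simulated noise was independent between genes, with the same SD in all groups for a gene and a correlation of 0.282 within a culture. The larger spread of the replicate 1 arrays was therefore not simulated. A held-out transmission ratio was also computed. In each of the 9 ways to hold out 1 shCtrl and 1 shERa culture, the 500 genes with the smallest p in the other 4 cultures were chosen. The sum of their polysome changes in the held-out pair was divided by that of their cytosolic changes, each signed by its direction in the other cultures.

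Gene lists were written before the data were examined, and 41 of 42 had at least 5 measured genes. The list of mitochondrially encoded mRNAs had no measured member. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 41 lists of a comparison, and again with the correlation estimated from the data. None of the list calls in the 4 comparisons passed with an estimated correlation, so that adjusted p is printed beside each. Named genes were chosen by a rule fixed before the data were examined. It took Esr1 always. It took the 8 largest rises and the 8 largest falls per comparison among called genes whose groups did not overlap. It took up to 4 called members of each list with the smallest p, and the 6 genes with the smallest p per class and direction. Symbols that are only clone or model names, and microRNA, small nucleolar RNA (Snor), olfactory and vomeronasal receptor symbols, were passed over, so every ranking in the report is among the other genes. Members of a list could also be named with their values where none passed.

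The replicate numbers were checked for pairing. The deviations from the group means of the cytosolic and the polysome array of a culture correlated across genes in all 6 cultures (r = 0.559, 0.332 and 0.264 for shCtrl 1, 2 and 3, and 0.490, 0.318 and 0.369 for shERa 1, 3 and 4). The arrays were each other's best match in 5 of the 6, all but shCtrl 3. By the rule that every correlation exceeds 0.1, the number was taken to pair the RNA types of a culture, which the parallel isolation also implies. Between shCtrl and shERa only numbers 1 and 3 are shared.

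The fit, the classes, the held-out ratio and the list test were tested on simulated data with known answers for 20405 genes. Only a small part of these genes was given a change, so the shares below rest on few genes. Of simulated 2-fold changes, 82.9% were called in cytosolic RNA, 92.0% in polysome-associated RNA and 61.5% of offset genes by the interaction. Of simulated 4-fold changes these shares were 97.3%, 100% and 91.7%. Among genes without a simulated change, 6 were called in cytosolic RNA, 10 in polysome-associated RNA and 1 by the interaction. The alternatives tried were another quantile normalization, centring on array medians, a filter on dim rows, all rows, a trended and robust variance model, array weights, a looser threshold of 0.15, replicate number or culture as a block, regression of one RNA type on the other, only the arrays of 1 RNA type, and leaving out each culture. After the data had been seen, fits without both replicate 1 cultures and a regression of the cytosolic on the polysome value were added. Figures were drawn with matplotlib 3.10.9.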

Results

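The study measured how loss of the estrogen receptor alpha changes mRNA levels and the loading of mRNA on polysomes in PTEN-deficient mouse prostate cancer cells. BM67 cells with a control shRNA (shCtrl) or an shRNA against Esr1 (shERa) were compared in total cytosolic RNA and in RNA bound by more than 3 ribosomes, with 3 arrays in each of the 4 groups. Arrays of one group correlated at r of 0.9906 or more across genes. The 4 arrays of replicate 1 stood apart from the others of their groups: their residual SD ranged from 0.236 to 0.271 on the log2 scale, against 0.162 to 0.210 for the other 8 arrays.

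Esr1, the targeted gene, fell in both RNA types. In cytosolic RNA its value was 7.89 ± 0.09 (SD, n = 3) in shCtrl cells and 6.34 ± 0.15 (SD, n = 3) in shERa cells on the log2 scale, a fall of 2.93-fold. The shCtrl arrays read 7.98, 7.90 and 7.79 and the shERa arrays 6.39, 6.17 and 6.46. The log2 change was -1.55 (SE 0.10, limma adjusted p = 7.6e-06). In polysome-associated RNA the value was 8.27 ± 0.10 (SD, n = 3) in shCtrl and 6.54 ± 0.06 (SD, n = 3) in shERa cells, a log2 change of -1.73 (SE 0.10, limma adjusted p = 4.1e-06). The 2 falls were not distinguishable (interaction -0.18, SE 0.14, limma adjusted p = 0.615).

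Postn, Pdgfrb and Npffr1 had the deepest falls in cytosolic RNA of shERa cells among the genes named. Postn, which encodes the matrix protein periostin, fell by 4.31 on the log2 scale, the receptor gene Pdgfrb fell by 4.16 and the collagen gene Col1a2 fell by 3.62 (SE 0.30, 0.24 and 0.14). Npffr1 (-3.91), Cd200 (-3.68), Col6a2 (-3.43), Chst11 (-3.25) and Fam20a (-3.25) completed the 8 largest falls among genes the naming rule allows. Among genes the naming rule allows, the largest rises were those of Fam183b (3.26), Zfp605 (3.12), Xlr (3.05), Zfp991 (3.03), Hmgn5 (2.88), Ugt2b34 (2.66), Aff2 (2.62) and Igsf11 (2.56). The control means of Fam183b (3.97), Xlr (3.07) and Aff2 (3.95) lay below the background level of 4.00, so the size and rank of their changes are uncertain. In total 3229 of 20405 genes changed, 1544 higher and 1685 lower, and 401 of the higher and 238 of the lower genes changed more than 2-fold. The count depended on single cultures: it was 1829 without shCtrl replicate 2, 1938 without shCtrl replicate 3 and 2021 without shERa replicate 4. It was 5340 with array weights, which count the replicate 1 arrays less.

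Among the lists fixed beforehand, extracellular matrix and collagen genes showed the clearest fall. Of 36 measured members 20 fell and 1 rose (22 and 1 adjusted over the list alone). Col12a1 (-2.26) and Col5a1 (-1.04) fell with Postn and Col1a2, while Lama5, a laminin of epithelial basement membranes, rose by 1.42. The list's median was -0.50 (camera adjusted p = 2.8e-11, adjusted p = 0.245 with an estimated correlation). Of 13 fibroblast and smooth muscle markers 5 fell (6 adjusted over the list alone), Col1a2, Pdgfrb, Acta2 (-1.74), Col3a1 (-0.95) and Col1a1 (-0.42), with a camera adjusted p = 0.000793 and an adjusted p = 0.320 with an estimated correlation. Of the 18 mesenchymal genes Fn1 (-1.80), Itga5 (-0.75) and Acta2 fell and Zeb2 rose by 1.30, and the list was not called (camera adjusted p = 0.442). Genes for antigen presentation on MHC class I fell in 6 of 15 cases (6 lower and 1 higher adjusted over the list alone), among them the peptide transporter genes Tap1 (-1.68) and Tap2 (-1.44) and the immunoproteasome genes Psmb8 (-1.5) and Psmb10 (-0.76). The camera adjusted p was 0.000206, and the adjusted p = 0.320 with an estimated correlation.

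Known estrogen-responsive genes went both ways. Of 37 measured, 6 fell and 2 rose, the same numbers as adjusted over the list alone, and the list was not called (camera adjusted p = 0.507). Greb1, a classical estrogen receptor target, fell by 1.93 (SE 0.26), Myb fell by 1.06, Ret fell by 0.90 and Siah2 fell by 0.77. Krt19 rose by 1.69. Krt19 is also among the prostate luminal markers, of which it, Psca (1.08) and Foxa1 (0.69) rose, 3 of 11 measured (4 adjusted over the list alone). That list was called at a camera adjusted p = 0.0487 with an adjusted p = 0.433 with an estimated correlation, and the call was lost without replicate 1 of either shRNA, without shERa replicate 4 and after either rescaling (camera adjusted p = 0.114, 0.0763, 0.0909, 0.0542 and 0.0501). Among 12 basal markers Itgb4 (1.01), Dst (0.82) and Itga6 (0.89) rose and Trp63, the master regulator of basal cells, fell by 1.10. Of 21 androgen-responsive genes Ell2 (0.93) and Tpd52 (0.37) rose (none adjusted over the list alone, camera adjusted p = 0.507). By limma no marker of endothelial cells (12 measured), macrophages (15) or T cells (11) changed, and at an unadjusted p under 0.05 only 1 macrophage marker was lower. Of these markers only 6, 8 and 4 lay above background, and a fall of the others could hardly be seen.

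Some genes of mitosis were among those that rose in cytosolic RNA. Of 26 G2/M genes 8 rose (10 adjusted over the list alone), including the kinetochore genes Cenpe (1.74) and Cenpf (1.47), Hmmr (1.11) and Nusap1 (1.02), with a camera adjusted p = 0.000206 and an adjusted p = 0.638 with an estimated correlation. Ribosomal protein genes fell in 9 of 35 cases (10 adjusted over the list alone), Rps14 by -1.38, Rps10 by -0.92 and Rps3 by -0.60. Proteasome genes fell in 10 of 30 cases and rose in 3 (12 and 3 adjusted over the list alone), with Psma7 at -1.07, Psmb6 at -0.76 and Psmd7 at -0.72. Oxidative phosphorylation genes fell in 17 of 61 cases and rose in 2 (20 and 3 adjusted over the list alone), with Cox4i1 at -1.02 and Ndufa9 at -0.56. Of the glycolysis genes 7 of 18 fell (10 adjusted over the list alone), among them the phosphofructokinase genes Pfkl (-0.93) and Pfkm (-0.90). Of the cholesterol synthesis genes 7 of 19 fell (7 adjusted over the list alone), among them Mvd (-0.98) and Pmvk (-0.85). Replication-dependent histone genes fell in 7 of 30 cases (10 adjusted over the list alone), with H2bc18 at -1.03. The camera adjusted p values for these 6 lists, in that order, were 0.000791, 0.00605, 0.00345, 0.000299, 0.000793 and 0.000269, and each had an adjusted p = 0.638 with an estimated correlation. After renewed quantile normalization the proteasome list was not called (camera adjusted p = 0.0642), with the same direction.

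In polysome-associated RNA Postn fell by 4.22, Pdgfrb fell by 3.96, Col1a2 fell by 3.76 and Npffr1 fell by 3.74 on the log2 scale, followed by Nt5e (-3.11), Cd200 (-3.11), Chst11 (-2.96) and Fam20a (-2.83). Cdx2, a homeobox gene of intestinal epithelium, rose most (3.01, SE 0.18), followed by Ptprf (2.29), Dusp22 (2.24), Igsf11 (2.23), Ccn3 (2.20), Tspan15 (2.20), Wnt4 (2.19) and Cyb561 (2.07). Of 20405 genes 702 changed, 299 higher and 403 lower. This count was 384 without shCtrl replicate 2, 350 without shCtrl replicate 3, 419 without shERa replicate 3 and 310 without shERa replicate 4. With only the 6 polysome arrays it was 381, and without both replicate 1 cultures it was 2014.

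Matrix genes fell in 14 of 36 cases and rose in 1 (19 and 1 adjusted over the list alone), with Col12a1 at -2.26, Col3a1 at -1.39 and the rising Lama5 at 1.73 (camera adjusted p = 1.9e-18, adjusted p = 0.0603 with an estimated correlation). Fibroblast and smooth muscle markers fell in 3 of 13 cases, Col1a2, Pdgfrb and Col3a1 (4 adjusted over the list alone; camera adjusted p = 9.2e-07, adjusted p = 0.0605 with an estimated correlation). Fn1 (-1.73) and Itga5 (-0.53) fell among the 18 mesenchymal genes (5 adjusted over the list alone), which were called as a list (camera adjusted p = 0.00216, adjusted p = 0.0625 with an estimated correlation). Tap1 (-1.19), Tap2 (-1.11), Psmb8 (-1.38), Psmb9 (-1.17) and Psmb10 (-0.58) were the 5 of 15 antigen presentation genes that fell (5 adjusted over the list alone; camera adjusted p = 1.2e-05, adjusted p = 0.141 with an estimated correlation). The unfolded protein response list had 1 falling member of 21, Atf3 (-0.80), with 3 adjusted over the list alone and a median of -0.20 (camera adjusted p = 2.8e-05, adjusted p = 0.394 with an estimated correlation). Tars (-0.60) was the 1 of 19 aminoacyl-tRNA synthetase genes that fell, 3 adjusted over the list alone (camera adjusted p = 0.000125, adjusted p = 0.872 with an estimated correlation). The luminal markers Krt19 (1.96) and Foxa1 (0.57) rose, 2 of 11 (5 adjusted over the list alone; camera adjusted p = 0.0211, adjusted p = 0.148 with an estimated correlation). That call was lost without shCtrl replicate 3 (camera adjusted p = 0.0628). Of 37 estrogen-responsive genes 3 fell and 2 rose (4 and 3 adjusted over the list alone), with Greb1 at -2.51, Ret at -1.01 and Krt19 rising, and the list was not called (camera adjusted p = 0.998).

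**Figure D1:**
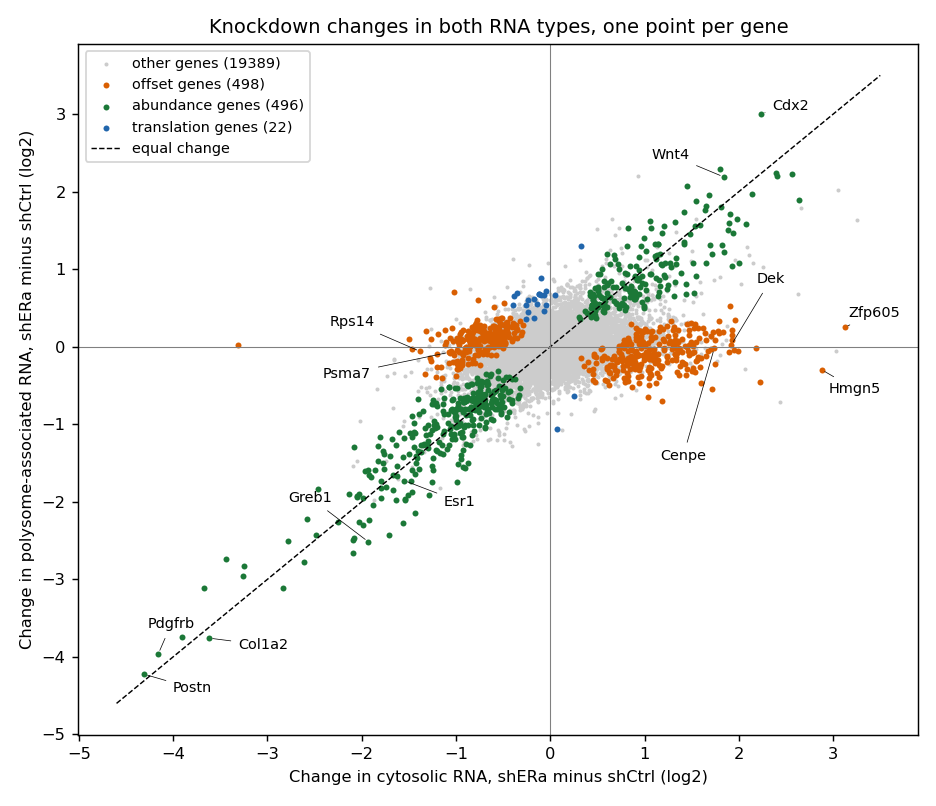
Log2 change by Esr1 knockdown in cytosolic RNA (x axis) against polysome-associated RNA (y axis), 1 point per gene for 20405 genes. The 496 abundance genes (green) follow the dashed line of equal change, while the 498 offset genes (orange) spread along the horizontal line of no polysome change and the 22 translation genes (blue) lie off it near a cytosolic change of 0. The class definitions largely set these positions.

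For many genes the cytosolic change was larger than the change on polysomes, by a tested interaction. Hmgn5, which encodes a nucleosome-binding protein, rose by 2.88 in cytosolic RNA and stood at -0.30 in polysome-associated RNA, an interaction of -3.17 (SE 0.35, limma adjusted p = 0.00668). Zfp605 (cytosolic 3.12, polysome 0.25), Esco2, a cohesin acetyltransferase gene (1.99, -0.05), Mybl1 (1.79, 0.18), Lrif1 (1.38, -0.04) and Glmn (1.32, -0.09) showed the same form. In the opposite direction Wdr34 (cytosolic -0.88, polysome 0.20), Ccs, the copper chaperone of superoxide dismutase (-1.11, 0.03), Pfdn5 (-1.07, 0.11), Dok1 (-0.70, 0.10), Psma7 (-1.07, -0.07) and Ubac1 (-0.87, 0.12) fell in cytosolic RNA and did not pass in polysome-associated RNA. Such offset genes numbered 498. Of them, 265 had higher cytosolic RNA, with median changes of 1.05 in cytosolic and -0.10 in polysome-associated RNA, and 233 had lower cytosolic RNA, with medians of -0.72 and 0.10.

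By comparison, 496 abundance genes passed in both RNA types with the same sign and not for the interaction, which does not show equal change. Of these genes, 183 were higher and 313 lower. They included Esr1, Postn, Pdgfrb, Col1a2, Col12a1, Col3a1 and Fn1, and on the higher side Mpzl2, Rasef, Epb41l4b, Cdx2, Dusp22 and Rapgef5. Only 22 were translation genes, 20 higher and 2 lower. Snrnp35 (polysome 0.54, cytosolic -0.26), Gtpbp6 (0.67, -0.07), Dedd2 (0.56, -0.15), Fastkd2 (0.61, -0.18), Slc25a25 (0.54, -0.40) and Sgsm2 (0.36, -0.26) rose on polysomes. Bms1, a gene for ribosome assembly (-0.64, 0.26), and Nfat5, the osmotic stress factor (-1.06, 0.07), fell there. Single cultures moved these counts: abundance genes numbered 301 without shCtrl replicate 2, 279 without shCtrl replicate 3, 323 without shERa replicate 3 and 242 without shERa replicate 4, and translation genes 0, 0, 0 and 2 in the same order and 38 without shERa replicate 1. Without both replicate 1 cultures there were 1034 abundance and 236 translation genes. The trended and robust variance model left 9 translation genes. Regression of the polysome on the cytosolic value, which found 37.5% and 84.6% of simulated 2-fold and 4-fold translation genes, called 0 genes. The effect of the opposite regression, with a slope fitted per gene, had the opposite sign to the interaction in Dedd2 and Fastkd2.

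The interaction passed in 556 genes, 268 higher and 288 lower. Among genes the naming rule allows, the largest falls of polysome association after Hmgn5 and Zfp605 were those of Esf1 (-2.67), Ube2v2 (-2.26), Ifi203 (-2.20), Esco2 (-2.04), Zfp729b (-1.99) and Zfp518a (-1.97). The largest rises among them were those of Ccl27a (1.73), the mitochondrial ribosome gene Mrps27 (1.60), Bcl7c (1.51), Cops9 (1.44), Rcc1l (1.37), Dohh (1.35), Mrpl53 (1.34) and Rps14 (1.32). The small nucleolar RNA Snord57 (interaction 3.34, cytosolic -3.32) and the model gene Gm10509 (-3.15), which the rule passes over, ranked among the largest and are named after their values were seen. With culture as a random block, which pairs the RNA types of a culture, the interaction passed in 1488 genes (753 higher, 735 lower), and with culture as a fixed block in 1838. The calls depended on single cultures: 1 gene passed without shCtrl replicate 2, 1 without shCtrl replicate 3, 1 without shERa replicate 3 and 44 without shERa replicate 4, while 964 passed without shCtrl replicate 1 and 1747 without both replicate 1 cultures. The offset genes numbered 0, 1, 1, 41, 867 and 1269 in the same order. With culture as a random block there were 1181 offset and 49 translation genes. The trended and robust variance model gave 335 interaction and 312 offset genes. Regression of the polysome on the cytosolic value called 0 genes (1903 at an unadjusted p under 0.05), and in simulated data it found no offset gene. Its effect, with a slope fitted per gene, had the opposite sign to the interaction in 15 named genes, among them Hmgn5, Esf1 and Cops9.

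**Figure D2:**
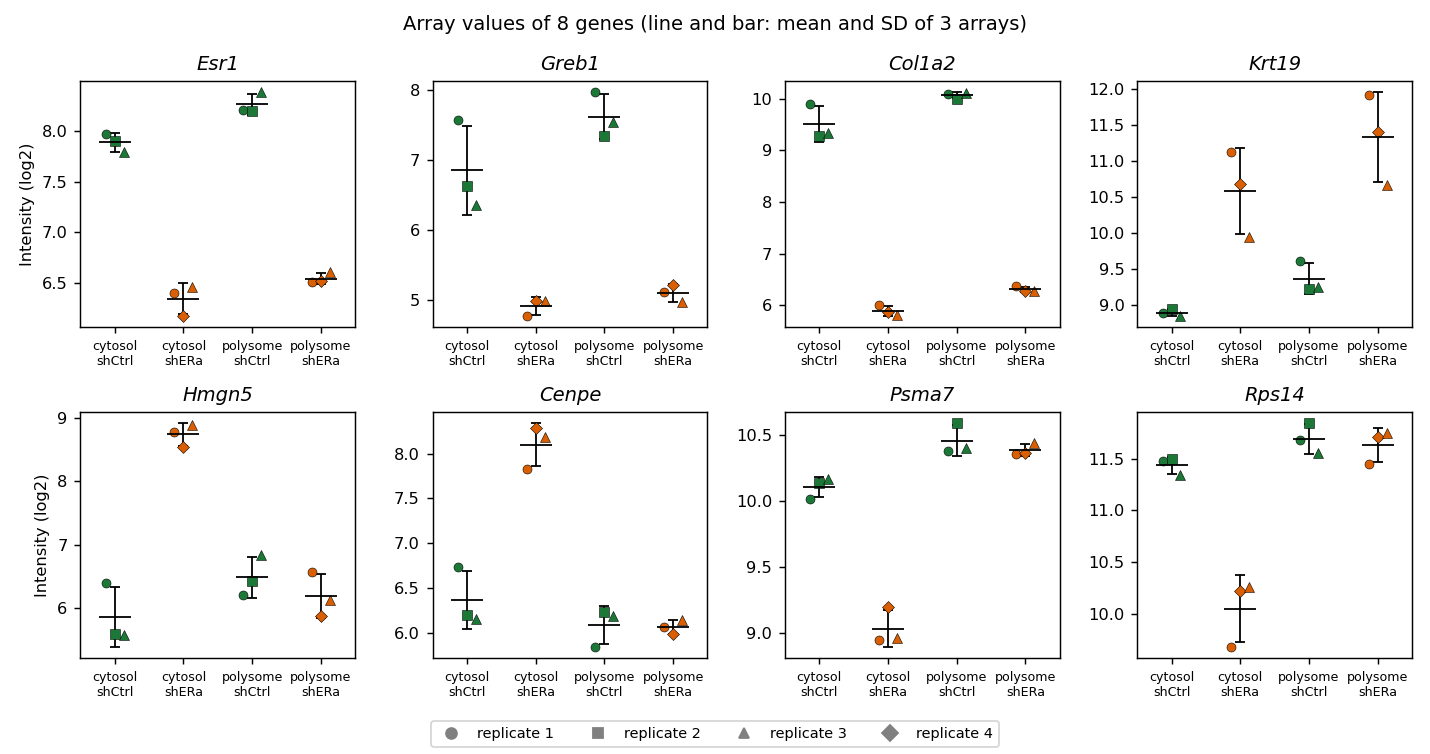
Array values (log2 intensity) of 8 genes in the 4 groups, with replicates by symbol and the mean and SD of 3 arrays as a line and bar. Esr1, Greb1, Col1a2 and Krt19 shift in both RNA types, whereas Hmgn5, Cenpe, Psma7 and Rps14 shift in the cytosolic arrays of shERa cells, with interactions of -3.17, -1.76, 1.00 and 1.32.

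The interaction was also tested for the gene lists. It holds the cytosolic change with a minus sign, so opposite signs in the cytosolic and the interaction test are expected from shared arrays alone. None of the 8 lists called for the interaction was called in polysome-associated RNA. There no G2/M, proteasome, ribosomal protein or oxidative phosphorylation gene passed, with list medians of -0.07, 0.05, 0.02 and 0.02. In the fit of all cultures, a gain or loss of polysome association in these lists therefore mostly reflects the cytosolic change. The glycolysis list, in contrast, had a polysome median of -0.23, with 1 of 18 genes lower. Without both replicate 1 cultures, the glycolysis and cholesterol lists were called lower in polysome-associated RNA (camera adjusted p = 0.00399 and 0.0145). The oxidative phosphorylation list was called higher there (camera adjusted p = 0.0245), and the other lists were not called. G2/M genes lost polysome association in 5 of 26 cases (8 adjusted over the list alone): Cenpe (-1.76), Hmmr (-1.32), Cenpf (-1.32) and Kif11 (-1.31) were among them, with a median of -0.36 (camera adjusted p = 7.4e-06, adjusted p = 0.968 with an estimated correlation). Proteasome genes gained it in 6 of 30 cases (11 higher and 3 lower adjusted over the list alone), among them Psma7 (1.00), Psmc2 (0.91), Psmc3 (0.88) and Psmb6 (0.85). Ribosomal protein genes gained it in 4 of 35 cases, Rps14, Rps10 (1.01), Rps3 (0.71) and Rplp1 (0.65), 8 adjusted over the list alone. Oxidative phosphorylation genes gained it in 5 of 61 cases (12 adjusted over the list alone), among them Cox4i1 (0.91), Ndufa9 (0.71) and Atp5c1 (0.62). Mvd (1.04) was the called gene of 19 in cholesterol synthesis and Pfkl (0.70) the called gene of 18 in glycolysis, with 4 each adjusted over the list alone. The camera adjusted p values of these 5 lists, in that order, were 0.00289, 0.00615, 0.00943, 0.0198 and 0.0226, and each had an adjusted p = 0.968 with an estimated correlation. In the histone and tricarboxylic acid cycle lists no gene passed by limma (8 of 30 and 6 of 19 were higher at an unadjusted p under 0.05), while the lists were called with medians of 0.35 and 0.23 (camera adjusted p = 0.00821 and 0.0228, adjusted p = 0.968 for both with an estimated correlation). The tricarboxylic acid cycle call was lost with culture as a fixed block (camera adjusted p = 0.0509). The G2/M and ribosomal protein lists kept their calls when any one culture was left out, and the other 6 lists each lost theirs without at least 1 culture. After renewed quantile normalization the oxidative phosphorylation, cholesterol and glycolysis lists (camera adjusted p = 0.062 each) and the tricarboxylic acid cycle list (0.117) were not called, with the same direction.

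The change in polysome association of a gene shares its cytosolic arrays with the cytosolic change, so the relation between the RNA types was set against chance. Across genes, which are not independent replicates, cytosolic and polysome changes correlated at r = 0.518. The mean was 0.284 in simulations with no effect and 0.867 in simulations that carried the cytosolic changes of called genes over in full. The covariance of cytosolic change and interaction was -0.105, against -0.0204 with no effect. No offset gene arose in any of the 50 simulations of either kind, whose noise was independent between genes. Of the 702 genes called in polysome-associated RNA, 72.5% were also called in cytosolic RNA with the same sign. Of the 3229 genes called in cytosolic RNA, 15.8% were also called in polysome-associated RNA with the same sign. A difference of calls does not test a difference between RNA types: of the 2713 genes called only in cytosolic RNA, 2215 did not pass for the interaction. Both were higher for 194 genes and both lower for 315, where independent calls would give 22.6 and 33.3. The RNA types share cultures and the estimate of spread, so their calls are not independent even without a shared effect. In held-out cultures, genes chosen from cytosolic RNA showed a median of 0.446 of their cytosolic change on polysomes (range 0.315 to 0.526 over 9 folds). Genes chosen from polysome-associated RNA had a median ratio of 1.03 (range 0.814 to 1.12).

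**Figure D3:**
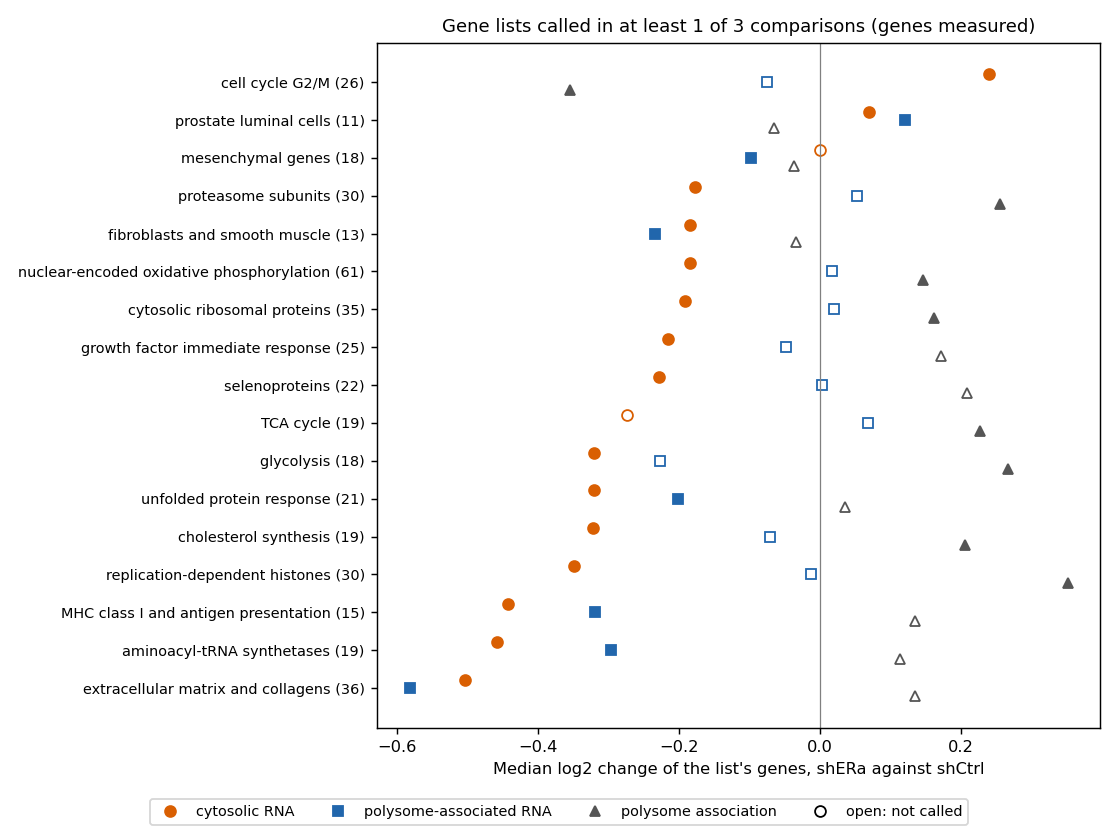
Median log2 change of the measured genes of each list called in at least 1 of the 3 knockdown comparisons, with the number of genes in parentheses. Filled symbols passed camera with the preset correlation at an adjusted p under 0.05 and open symbols did not; none passed with an estimated correlation. The G2/M list stands at 0.24 in cytosolic RNA and -0.36 in polysome association, and the matrix list at -0.50 and -0.58 in the 2 RNA types.

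In control cells, polysome-associated RNA was set against total cytosolic RNA to show which transcripts the heavy fractions hold. Several histone mRNAs were richer on polysomes: H3c1 (2.10), H4c2 (1.74), H4c3 (1.37), H4f16 (1.34) and H4c6 (1.34) were among the 8 largest positive differences, with Scarna13 (2.93), Naglu (1.36) and Nptxr (1.33). Selenow (-2.49), Coa5 (-2.27), the nuclear RNA Malat1 (-2.25), the small nucleolar RNA gene Rnu3a (-2.19), Dph3 (-1.96) and Hivep1 (-1.92) were poorer there, as were the histone genes H3c14 (-2.27) and H3c15 (-2.16). The cytosolic mean of H3c1 and the polysome mean of H3c15 (3.42 each) lay below the background level of 4.00, so the size and rank of these differences are uncertain. In total 5014 genes differed, 2660 higher and 2354 lower on polysomes, of which 109 and 416 by more than 2-fold. The count was 2707 without shCtrl replicate 2 and 2371 without shCtrl replicate 3.

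Ribosomal protein mRNAs were poorer on polysomes than in cytosolic RNA in 12 of 35 cases (13 adjusted over the list alone), with Rpl27a at -1.51, Rps10 at -1.05, Rplp1 at -0.73 and Rplp0 at -0.44 (camera adjusted p = 6.8e-05, adjusted p = 0.715 with an estimated correlation). Among the other mRNAs with a 5' terminal oligopyrimidine tract, Pabpc1 (-1.51), Eif3f (-0.63) and Eif4b (-0.49) were poorer and Eef1g (1.03) was richer, 3 and 1 of 15, the same numbers as adjusted over the list alone (camera adjusted p = 0.0133, adjusted p = 0.715 with an estimated correlation). Of 30 histone genes 17 were richer and 2 poorer (20 and 2 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.715 with an estimated correlation). Genes of the microRNA machinery were poorer in 8 of 13 cases and richer in 1, the same numbers as adjusted over the list alone. Dicer1 (-1.17), Drosha (-1.06), Tnrc6a (-0.80) and Tnrc6c (-0.75) were among them (camera adjusted p = 0.00174, adjusted p = 0.312 with an estimated correlation). G2/M genes were poorer in 7 of 26 cases (10 adjusted over the list alone), Nusap1 (-1.23), Anln (-0.76) and Tpx2 (-0.72) among them (camera adjusted p = 0.00298, adjusted p = 0.715 with an estimated correlation). Of 12 nuclear or untranslated RNAs Malat1, Gas5 (-1.18) and Rpph1 (-1.11) were poorer (4 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.355 with an estimated correlation). Antigen presentation genes were richer in 6 of 15 cases and poorer in 2 (9 and 2 adjusted over the list alone), Tap1 (1.11) and Tap2 (0.77) among them (camera adjusted p = 0.0272, adjusted p = 0.715 with an estimated correlation). With culture as a fixed block the ATF4 and amino acid response list was called as well (camera adjusted p = 0.0106; without the block 0.0615, and adjusted p = 0.715 with an estimated correlation), with Trib3 at 1.11 and Sesn2 at 0.93. The call of the terminal oligopyrimidine list was lost without shCtrl replicate 1 (camera adjusted p = 0.0856), and that of antigen presentation without shCtrl replicate 3 (camera adjusted p = 0.0545).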

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

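The tests on nuclear RNA, on fibroblast markers and on held-out cultures other than replicate 1 were chosen, and their bounds written, after the results had been seen. A first version of the marker test, with all 10 markers above background, was replaced because several of them lay near background. The difference between RNA types stood out because the interaction tests it directly: 556 genes passed. In 7 genes the change passed in both RNA types with opposite signs: Id3, B9d2 and Rdm1 were lower in cytosolic and higher in polysome-associated RNA, as was the model gene Gm11487, and Hs6st2, Zfp449 and the model gene Gm10509 were the reverse. All but Id3, which the rule names, were chosen after their values were seen, and all means of Gm11487 and both polysome means of Gm10509 lay below the background level of 4.00, so those changes are uncertain. The lists called for the interaction with the preset correlation had median changes of 0.161 (ribosomal proteins), 0.351 (histones), -0.355 (G2/M), 0.267 (glycolysis), 0.227 (tricarboxylic acid cycle), 0.146 (oxidative phosphorylation), 0.205 (cholesterol synthesis) and 0.255 (proteasome), each with an adjusted p = 0.968 with an estimated correlation. Among the 710 rows without a gene symbol, which no comparison of the report used, 130 passed in cytosolic RNA, 30 in polysome-associated RNA, 29 for the interaction and 164 between RNA types in control cells.

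Cytosolic changes that were smaller or absent on polysomes were weighed against 3 technical explanations. Larger measurement error of the polysome arrays would leave a held-out ratio of 0.8 or more for offset-like genes, and the median ratio was -0.0282 (range -0.185 to 0.105 over 9 folds), which argues against it. The axis on which the replicate 1 cultures stand apart is argued against as well: in the 4 folds whose held-out cultures were not replicate 1 the median ratio was 0.0259 (range -0.0514 to 0.105), while the mean cytosolic change there was 0.865 to 1.08. Nuclear RNA in the cytosolic RNA of the shERa cultures cannot be told apart, because the 10 nuclear or untranslated RNAs above background went both ways. Of them 5 were higher and 5 lower (median -0.192, SD 0.759). Rny3 (-1.73), Rpph1 (-0.95) and Rmrp (-0.85) fell, while the largest rises, Tug1 (0.78) and Malat1 (0.40), did not pass. A difference in handling between the shERa and shCtrl cytosolic preparations is confounded with the knockdown and was not tested.

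The fall of matrix genes and fibroblast markers was weighed against 2 explanations. Fewer fibroblast-like cells in the shERa cultures would lower all their markers alike, and the SD of the 6 markers well above background was 11.57 times their median standard error, from Pdgfrb (-4.16) and Col1a2 (-3.62) to Col1a1 (-0.42) and Pdgfra (-0.41, not passing). All 6 had a log2 change below -0.1, 5 of them passing, and other cells of the culture could express the markers that moved least, so this cannot be told apart. An off-target effect of the shRNA, or a difference between the transduced pools, cannot be told apart either, since the labels name 1 shRNA against Esr1.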

How the results depend on the processing

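Esr1 kept its fall under every alternative (without each culture in turn -1.61 to -1.46 in cytosolic and -1.76 to -1.67 in polysome-associated RNA). Of the values of named genes under the alternatives 5589 kept direction and call, 755 kept only the direction and 17 reversed. The reversals were all under the regressions of one RNA type on the other, whose effect is not the interaction itself. Of the counts by direction 124 stayed within 1.5 times and 112 did not. All 37 list calls were lost with an estimated correlation, 1 of 15 with culture as a fixed block and 7 of 37 without both replicate 1 cultures, while rescaling and leaving out single cultures kept 265 of 296, and no direction turned. Rescaling by quantiles or medians and testing all rows left every main count within 1.5 times. Signal over background limits dim genes: 13602 of 20405 lay above the olfactory receptor level. Where no construction is named, the cause was not tested.

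The trended and robust variance model gave 335 interaction, 312 offset and 9 translation genes. Array weights gave 5340 cytosolic, 1624 interaction, 1389 offset and 91 translation genes. The threshold of 0.15, looser by construction, gave 4995 cytosolic, 1387 polysome, 1580 interaction and 7720 control fraction genes, with 1296 offset, 818 abundance and 121 translation genes. With only the 6 polysome arrays 381 genes passed, whereas with only the 6 cytosolic arrays 3229 passed, 2803 of them shared with the fit of 12 arrays. Chosen after the data had been seen, the fit without both replicate 1 cultures gave 2014 polysome, 1747 interaction, 1269 offset, 1034 abundance and 236 translation genes. The held-out ratio was 0.641 with 100 and 0.324 with 2000 genes, and for genes chosen from polysome-associated RNA 1.14 with 2000.

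Leaving out each culture in turn gave 1829 to 3790 cytosolic, 310 to 1030 polysome, 1 to 964 interaction, 2371 to 5600 control fraction, 0 to 867 offset, 242 to 635 abundance and 0 to 38 translation genes. For the held-out ratio no culture was left out entirely. Over the folds in which a given culture was not held out, its median ranged from 0.411 to 0.512. With genes chosen from polysome-associated RNA it ranged from 0.979 to 1.08. In those folds the given culture still helped to choose the genes. At an unadjusted limma p under 0.05 the interaction had 2287 genes without shCtrl replicate 2, 2505 without shCtrl replicate 3, 2537 without shERa replicate 3 and 2640 without shERa replicate 4.

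Culture as a random block gave 1488 interaction, 1181 offset and 49 translation genes, and as a fixed block 1838 interaction genes. Pairing by culture changed no other main count by over 1.5 times and no other list call than those given in the report. Across the shRNAs only numbers 1 and 3 are shared, and same-numbered arrays correlated at 0.407 and 0.152 in cytosolic and 0.0989 and -0.0978 in polysome-associated RNA. Number 1 was the best match in both RNA types and number 3 in neither, a hint from the data and not from the design, and with both polysome correlations under 0.1 they were not treated as pairs. With the number as a block there were 914 interaction, 779 offset and 42 translation genes. The planned regression of the polysome on the cytosolic value called 0 interaction genes (1903 at an unadjusted p under 0.05), and in simulated data it found none of the offset genes but 37.5% (2-fold) and 84.6% (4-fold) of the translation genes, so it gives the translation genes no support. Its slope was fitted per gene, where the interaction sets the slope at 1. Its effect is therefore another measure than the interaction. That effect had the opposite sign to the interaction in Cops9 (-0.21), Hmgn5 (0.65), Esf1 (0.27), Rps10 (-0.14), Rplp1 (-0.042), Cenpe (0.74), Hmmr (0.055), Cox4i1 (-0.17), Akt1s1 (-0.19), Psma7 (-0.026), Psmc2 (-0.015), Ago2 (0.12), Glmn (0.16), Ccs (-0.46) and Ubac1 (-1.31). The opposite regression, added after the data had been seen, called 2179 genes. Its effect had the opposite sign to the interaction in Dedd2 (-0.60) and Fastkd2 (-0.90).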

Other observations

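In cytosolic RNA of shERa cells 8 of 21 genes of the unfolded protein response fell and 1 rose (11 and 1 adjusted over the list alone), with Atf3 at -0.98, Herpud1 at -0.83, Hyou1 at -0.83 and the rising Ddit3 at 0.76 (camera adjusted p = 0.00064, adjusted p = 0.638 with an estimated correlation). Of 19 aminoacyl-tRNA synthetase genes 5 fell (8 lower and 1 higher adjusted over the list alone), among them Farsa (-0.97) and Kars (-0.79), with a camera adjusted p = 0.00146 and an adjusted p = 0.638 with an estimated correlation. Immediate response genes such as Ier2 (-1.07) and Spry1 (-1.01) fell in 5 of 25 cases and rose in 1, the same numbers as adjusted over the list alone. The selenoprotein genes Selenoh (-0.95), Sephs2 (-0.78) and Selenoo (-0.65) fell, 3 of 22 and also 3 adjusted over the list alone. These 2 lists were called at a camera adjusted p = 0.0432 and 0.0445, with an adjusted p = 0.638 each with an estimated correlation, and both calls were lost after renewed quantile normalization (0.0777 and 0.0705). The immediate response call was also lost without shCtrl replicate 1 (0.0591), shCtrl replicate 3 (0.0562) or shERa replicate 1 (0.211), and the selenoprotein call without shCtrl replicate 1 (0.114), shERa replicate 3 (0.0805) or shERa replicate 4 (0.0924).

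Other lists held changed genes without being called. Among 15 enzymes that modify the wobble uridine of tRNA, Nfs1 (-0.64) and Elp3 (-0.51) fell and Alkbh8 (0.84) rose (camera adjusted p = 0.188). The Notch ligand gene Jag1 fell in both RNA types (-1.76 and -1.38), with Notum (-1.56) and Hes1 (-0.74) lower and Znrf3 (0.50) higher in cytosolic RNA, 4 of 19 Wnt and Notch genes (camera adjusted p = 0.507). Of 18 hypoxia genes Egln3 (1.65 and 1.07) and Vegfa (0.76 and 0.56) rose in both RNA types and Slc2a1 (-0.66 and -0.49) fell in both (camera adjusted p = 0.911 in cytosolic RNA). Among 20 NRF2 targets Gsta3 (1.81 and 1.80) and the cystine transporter gene Slc7a11 (1.43 and 0.81) rose in both, and in cytosolic RNA 4 rose and 2 fell, Nqo1 (-0.65) and Gstp1 (-0.63) (camera adjusted p = 0.599). Ddit4, an inhibitor of mTOR signalling, fell by 1.83 in cytosolic RNA, where 3 of 27 genes of the PI3K, AKT and mTOR pathway fell and 2 rose (camera adjusted p = 0.608). In 13 genes of the microRNA machinery Ago2 rose by 1.21 in cytosolic RNA with an interaction of -1.23 (camera adjusted p = 0.122 in both comparisons). Dek, which had been placed in the list of translation initiation factors, rose by 1.92 with an interaction of -1.90. In that list 6 of 31 genes rose and 5 fell in cytosolic RNA (camera adjusted p = 0.856, and 0.68 for the interaction).

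The tests of Zfp genes and both tests within the genes with higher cytosolic RNA were chosen after the results had been seen. The first hypothesis is that zinc finger genes are over-represented among the offset genes with higher cytosolic RNA beyond what their intensity gives. Of these 265 genes 35 are named Zfp (13.2%), against a mean of 7.72 and a highest count of 19 in 10000 random sets matched on mean intensity (permutation p = 1e-04, the smallest possible), and among the 233 with lower cytosolic RNA there was 1 (random mean 3.47). Zfp genes were frequent among all cytosolic rises, with 92 of 350 higher and 23 lower. Against random sets drawn only from genes with higher cytosolic RNA, the mean was 18.6 and the highest count 33 (permutation p = 1e-04, the smallest possible). The second hypothesis is that genes with a long genomic span are over-represented there. The median span was 44.01 kb, against 22.8 kb in the random sets (permutation p = 1e-04, the smallest possible), and it was 11 kb for those with lower cytosolic RNA (23.3 kb at random). Against random sets of genes with higher cytosolic RNA, with a median of 39.5 kb, the 44.01 kb did not stand out (permutation p = 0.134), so a long span particular to offset genes was not shown. Both over-representations were found on the data that defined the classes, and genes are not independent replicates.

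For each of the 4 comparisons the 10 splits of 3 against 3 are too few for a share under 0.05, and the real split was the 1 with the most genes. The real count and the highest other were 3229 and 0 in cytosolic RNA, 702 and 27 in polysome-associated RNA, 556 and 0 for the interaction, and 5014 and 0 between RNA types in control cells. Every other split mixes arrays of the real groups, so real differences widen the spread within its groups and lower its count. These low counts are therefore no measure of chance.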
